A study of Homo sapiens with 12 samples.

How the data were processed

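Gene expression was measured in Ect1 cells, an immortalised line of human ectocervical epithelium, on 12 Affymetrix Human Genome U133 Plus 2.0 arrays, 4 each for medium alone, 10% seminal plasma and TGFB3 at 5 ng/ml, all after 10 h. Per the labels' protocols, cells were grown to confluence in serum-free keratinocyte medium with EGF and pituitary extract before the medium was changed, and RNA was extracted with Trizol and purified on columns. Per the series' design text, each of the 4 replicates of a treatment was a biological replicate that pooled a separate set of 4 wells. The labelling is described in more than one way, as a whole-transcript sense-strand method per the labels' protocols and as single-cycle labelling per the series' design text, and which was used stayed open. The labels give no batch, scan day or culture run.

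The deposited value table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes the tools were GCOS 1.4, MAS5, R 2.6.1, Partek and RMA, with no role or order. The values are all positive and unlogged, and the mean after trimming 2% at each end lay between 493.3 and 498.4 on every array, as a global scaling of MAS5 signals gives. The scale was thus read from the values, and no centring of genes was seen. The second table repeats the same intensity values (largest difference 0) and adds what the authors computed: the mean intensity of each group, a signed fold for each treatment against control, a p-value and a call. The deposited fold equals the ratio of the arithmetic group means of the linear signals within 0.011 for 99.92% and 99.98% of probe sets, with the negative reciprocal for falls. The test behind the deposited p-value is not given in the sources used here, and an equal-variance test of log2 signals between 2 groups matched it within 0.0006 for only 1.06% and 1.08% of probe sets. No column of other samples was left over (0 unused).

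Values under 16 were set to 16 and log2 was taken, as fixed in advance for linear values, so that fold changes of genes near the floor are understated. No further normalization and no filter on dim probe sets was applied. Of 54613 probe sets, 39873 carried 1 gene symbol in the deposited table, 1522 several, 13164 none, and 54 a symbol that a spreadsheet had turned into a calendar entry. The last 3 kinds were counted but not named. Of the symbols, 14655 were current in the RefSeq gene table, 2743 were older symbols that were updated through it, and 2350 were kept as deposited. For gene-level results each of 19682 genes was represented by the probe set with the highest mean over all 12 arrays. No genome was used here, so no coordinates are given.

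Comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without intensity trend or robust option) on all 12 arrays, with 1 mean of log2 values per treatment and 1 shared estimate of the spread, and Benjamini-Hochberg adjustment over all probe sets with a threshold of 0.05. The contrasts were seminal plasma versus control, TGFB3 versus control and seminal plasma versus TGFB3. Standard errors come from this shared estimate over all 12 arrays, so a gene has the same one in every contrast. They do not show the spread within the 2 groups compared. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. These choices, the gene lists and the rule for named genes were fixed before the data were examined.

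The 30 gene lists hold 534 genes, of which 527 were measured, and were written from general knowledge of squamous epithelium, TGF-beta signalling and the content of seminal plasma. Of these, 5 mark other cell types or carried-over RNA (leukocytes, sperm and testis, prostate and seminal vesicle, fibroblasts, columnar epithelium). Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with the correlation estimated per list and limma's fry beside it. For each list, calls were also counted after adjustment over its own members. List tests run on 1 probe set per gene. Mean signals printed beside genes are arithmetic means of the linear values, while fold changes come from the log2 values.

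The genes named were, for each treatment against control, the 8 largest rises and 8 largest falls among genes past the threshold whose 4 treated arrays all lay on one side of the 4 controls, and for the direct contrast the 5 largest each way by the same rule. From each list, up to 4 changed members with the largest change were named, or the 2 with the smallest p where none changed. CSF2, IL6, CXCL8, CCL20, PTGS2, SMAD7, TGFB1, TGFB3 and MT2A were named whatever their values. Some genes that the rule names are not reported here. List members named beyond these, such as MT1E, MT1F, MT1H, MT1X, TIMP1, SERPINE2, SREBF2, CDKN2B, TGFBR1, LOX, IFIH1, RIGI, IL33, TGFA and PLAU, were chosen after their values were seen.

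The overlap and correlation of the treatments' effects share the 4 controls. They were therefore set beside 100 draws of unchanged groups against those controls, beside the overlap of independent lists, and beside the 6 ways of giving each comparison 2 of the 4 controls.

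The scripts were tested on simulated data before use. In 54613 simulated probe sets with equal spreads, limma called 7% of 2-fold and 62% of 4-fold changes for seminal plasma versus control, with 2 false among 71 calls, and 11% and 63% for TGFB3 versus control, with 8 false among 82. With each group's own spread, as measured on these arrays, it called 21% and 72% for seminal plasma, with 104 false among 197 calls (52.8%), and 13% and 68% for TGFB3, with 19 false among 100. The seminal plasma group varied more than the others, which a shared estimate does not allow for. The number of unchanged probe sets that reach the real p cutoff was therefore drawn 20 times and is given beside each count, and a test with a separate spread per group was added. That test was an unequal-variance t-test without the eBayes moderation of limma. Its counts can thus differ from limma's through the lost moderation as well as through the unequal spreads. A simulated list of 20 genes shifted by 1 on the log2 scale had a camera adjusted p of 1.63e-23, and 6 of 200 unchanged lists had a p under 0.05. The simulated genes were drawn independently with equal spreads. This check therefore says nothing about the preset correlation in lists whose members vary together.

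The alternatives tried were the replicate number as a block, a filter for a log2 value of at least 5 on at least 4 arrays, an intensity trend with robust estimation, array weights, only the 2 groups compared, quantile normalization, median centring, leaving out probe sets marked as shared between transcripts, stricter thresholds, the mean over all probe sets of a gene, and leaving out each array in turn. Fits without seminal plasma replicates 3 and 4, floors of 32 and 100 and the separate spread per group were added after the data were seen.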

Results

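Ect1 cells, a human ectocervical epithelial line immortalised with papillomavirus oncogenes, were kept for 10 h at confluence in medium alone (control), in medium with 10% pooled human seminal plasma by volume, or in medium with recombinant TGFB3, a transforming growth factor beta, at 5 ng/ml. Transcripts were measured on 12 Affymetrix arrays, 4 for each of the 3 treatments, and each array read a separate biological replicate pooled from 4 wells. The number of arrays limits the precision of every value. Each array gave a linear signal for 54613 probe sets, of which 39873 carried a single gene symbol, for 19682 genes. The median signal was 97.1, 101.7, 93 and 88.1 in control replicates 1 to 4, and 107.1, 100.1, 94.3 and 94.9 in TGFB3 replicates 1 to 4. It was 103.8, 97.2, 177.6 and 131.5 in seminal plasma replicates 1 to 4.

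Seminal plasma replicates 3 and 4 stood apart from the other 10 arrays. In them, 8.01% and 12.8% of probe sets lay below a signal of 16, against 16.3% to 20.2% elsewhere. Their 100 brightest probe sets held 18.41% and 15.36% of the total signal, against 7.66% to 11.6%. The first principal component, with 51.3% of the variance, placed them at 148.6 and 133.3, while seminal plasma replicates 1 and 2 lay at 27 and -16.3 and the other 8 arrays between -48 and -27.1. Values without these 2 arrays are therefore given beside the gene groups below. Such fits keep 2 seminal plasma arrays, so a call can be lost through fewer arrays as well as through a smaller change.

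The first comparison asks which transcripts differ in ectocervical cells after 10 h with seminal plasma. The largest rise was that of MT1M, a zinc-binding metallothionein, whose mean signal was 35.8 in the controls and 13800 with seminal plasma. Its log2 fold change was 8.49 ± 0.56 (SE from the spread shared by all 12 arrays, 4 per group). Enzymes that degrade extracellular matrix followed: MMP1, the interstitial collagenase, rose by 5.82 ± 0.56 on the log2 scale (304 to 19600), and MMP10, a stromelysin, by 4.08 ± 0.42. IL13RA2, a decoy receptor for interleukin 13, rose by 5.16 ± 0.5, SCG5, a secretory chaperone, by 4.87 ± 0.42, SPOCD1 by 4.85 ± 0.22 and PMEPA1, a TGF-beta-induced inhibitor of SMAD signalling, by 3.86 ± 0.26. Genes of the interferon response fell: IFIT1 by 3.5 ± 0.66 (2250 to 229), RTP4 by 3.51 ± 0.27 and RSAD2 by 3.24 ± 0.7. By the rule that picked these genes, the 4 seminal plasma arrays lay on one side of the 4 control arrays. That separation therefore adds no support. MT1M, MMP1, IL13RA2, SCG5, SPOCD1, MMP10, PMEPA1 and RTP4 passed in each of 12 fits that left out 1 array, IFIT1 in 7 and RSAD2 in 2. Of 66 named genes called with seminal plasma, 19 passed in all 12 of these fits, 21 in more than 6 and 26 in 6 or fewer.

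With limma, 1608 of 54613 probe sets passed an adjusted p of 0.05, 948 of them higher and 660 lower with seminal plasma, and 630 genes did so, 362 higher and 268 lower. The limma adjusted p was 0.000149 for MT1M, 0.00127 for MMP1 and IL13RA2, 0.00204 for MMP10, 0.00059 for SCG5, 1.32e-05 for SPOCD1, 0.000149 for PMEPA1, 0.000266 for RTP4, 0.0271 for IFIT1 and 0.0412 for RSAD2. Without seminal plasma replicates 3 and 4, 539 probe sets passed, 319 higher and 220 lower, of which 339 were among the 1608, and IFIT1 and RSAD2 no longer passed (limma adjusted p 0.0885 and 0.068). The median log2 fold change over all genes was 0.11. Quantile normalization moved the median over all probe sets from 0.2 to 0.01 and median centring moved it to -0.19. After median centring 787 probe sets passed, 299 higher and 488 lower, so that the balance of higher and lower calls followed the scaling. When unchanged values were simulated with each group's own spread, a mean of 386.4 probe sets reached the same p cutoff, which is 24% of 1608. A test with a separate spread per group, which also lacks limma's moderation, called 11 probe sets. The count was 375, 493, 299 and 270 without control replicates 1 to 4, 8900 without seminal plasma replicate 2, 713 and 429 without seminal plasma replicates 3 and 4 in turn, and 842, 901 and 929 without TGFB3 replicates 2 to 4, which share the estimate of the spread.

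Metallothioneins and zinc transport genes rose as a group: 8 of 11 measured members rose, 1 fell and 2 did not pass, and adjusted over the list alone 10 rose and 1 fell. MT1M was joined by MT1E (1.67), MT1F (1.95), MT1G (2.1 ± 0.34), MT1H (1.55), MT1X (1.49) and MT2A (1.42 ± 0.27) on the log2 scale, and by SLC30A1, which exports zinc from the cell (2.27 ± 0.38; adjusted p 0.0188). SLC39A10, a zinc importer, fell by 2.91 ± 0.46. The adjusted p of limma's camera test was 1.89e-07, and adjusted p = 0.183 with an estimated correlation. The list median relative to the control mean was 1.42, 1.07, 2.28 and 1.91 in seminal plasma replicates 1 to 4, against -0.13 to 0.18 in the controls, and without replicates 3 and 4 the camera adjusted p was 6e-09. In that fit MT1M, MT1E, MT1F and SLC30A1 rose and SLC39A10 fell, while MT1G, MT1H, MT1X and MT2A did not pass (limma adjusted p 0.0918, 0.0734, 0.067 and 0.0745).

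Among 21 measured matrix proteases, plasminogen system genes and inhibitors, 6 rose, none fell and 15 did not pass, and adjusted over the list alone 10 rose and 2 fell. Besides MMP1 and MMP10, MMP3 (3.26 ± 0.42) and MMP9 (2.96 ± 0.57), which degrade matrix proteins, rose, as did the inhibitors TIMP1 (1.32) and SERPINE2 (2.19). As a list they had a camera adjusted p of 0.00504, and adjusted p = 0.363 with an estimated correlation. The list median was 1.21 and 0.73 in seminal plasma replicates 1 and 2 and 0.48 and 0.23 in replicates 3 and 4, and the list passed without the latter (camera adjusted p 6.73e-06). In that fit MMP1, MMP3, MMP10, TIMP1 and PLAU rose, and MMP9 (limma adjusted p 0.146) and SERPINE2 (0.0503) did not pass.

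Of 28 measured inflammatory cytokines and chemokines, 4 rose, none fell and 24 did not pass, while adjusted over the list alone 13 rose and 1 fell. The neutrophil-attracting chemokines CXCL3 (2.77 ± 0.53; 173 to 1230) and CXCL2 (2.35 ± 0.53), and the cytokines IL11 (2.7 ± 0.63) and IL6 (1.97 ± 0.42), rose. With 1 array left out they passed in 7 (CXCL3), 3 (CXCL2), 1 (IL11) and 5 (IL6) of 12 fits. CXCL8, the gene of interleukin 8, had a log2 fold change of 3.61 ± 1.09 and CCL20 one of 2.01 ± 0.62, and neither passed (adjusted p 0.0847 and 0.0883). CSF2, which encodes GM-CSF, did not pass either (0.92 ± 0.75; adjusted p 0.467). For the list, the camera adjusted p was 0.00119, and adjusted p = 0.363 with an estimated correlation. The list median was 0.99, 1.21, 0.98 and 1.12 in seminal plasma replicates 1 to 4, and the list passed without replicates 3 and 4 (camera adjusted p 2.17e-05). In that fit CXCL3, CXCL2, IL11 and IL6 did not pass (limma adjusted p 0.0503, 0.0537, 0.274 and 0.137), and the 1 member that rose was another, IL33 (0.0143).

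Of 19 measured EGF receptor ligands and MAPK feedback genes, 3 rose and 16 did not pass, and adjusted over the list alone 8 rose and 1 fell. The 3 were HBEGF, an EGF receptor ligand (2.43 ± 0.48), FOSL1, an AP-1 subunit (2.06 ± 0.35), and IER3 (1.84 ± 0.2). The camera adjusted p was 0.00562, and adjusted p = 0.363 with an estimated correlation. The list median was 1.35 and 1.06 in seminal plasma replicates 1 and 2, but 0.18 and 0.44 in replicates 3 and 4, while the controls ranged from -0.43 to 0.33, which includes replicate 3. The list passed without replicates 3 and 4 (camera adjusted p 1.92e-07), where IER3 (limma adjusted p 0.0199) and TGFA (0.0404) rose and HBEGF (0.0866) and FOSL1 (0.0607) did not pass.

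Of 25 measured epithelial-mesenchymal transition and matrix genes, 6 rose and 19 did not pass, and adjusted over the list alone 8 rose and 1 fell. They included the integrins ITGA2 (2.13 ± 0.27) and ITGA5 (1.55 ± 0.36), the actin-binding TAGLN (1.79 ± 0.31), the laminin chain LAMB3 (1.55 ± 0.26) and the transcription factor SNAI2 (0.98 ± 0.23). The camera adjusted p was 0.0399, and adjusted p = 0.363 with an estimated correlation. The list median was 0.48, 0.53, 0.58 and 0.28 in seminal plasma replicates 1 to 4, and without replicates 3 and 4 (camera adjusted p 0.000521) ITGA2 and LAMB3 rose and ITGA5, TAGLN and SNAI2 did not pass (limma adjusted p 0.0998, 0.091 and 0.127).

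Of 27 measured interferon-stimulated genes, 8 fell, none rose and 19 did not pass, and adjusted over the list alone 15 fell. They included IFIT1, RSAD2, OASL (-2.29 ± 0.35), OAS2 (-2.23 ± 0.46), OAS1 (-1.94 ± 0.44) and USP18 (-2.81 ± 0.66), all induced by interferons, and USP18 lay at the floor in 2 seminal plasma arrays. Toward lower values, the camera adjusted p of the list was 8.17e-10, and adjusted p = 0.363 with an estimated correlation. The list median was -1.41, -0.6, -1.01 and -1.07 in seminal plasma replicates 1 to 4, against -0.16 to 0.18 in the controls, and the list passed without replicates 3 and 4 (camera adjusted p 3.42e-10). In that fit IFIT1, RSAD2, OASL, OAS2, OAS1 and USP18 did not pass (limma adjusted p 0.0885, 0.068, 0.0795, 0.196, 0.229 and 0.276), and the 2 members that fell were IFIH1 (0.0394) and RIGI (0.0346), sensors of viral RNA. With 1 array left out OASL passed in 12 of 12 fits, OAS2 in 4, USP18 in 2 and OAS1 in 1.

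Among 23 measured genes of cholesterol synthesis and uptake, 4 fell, 1 rose and 18 did not pass, and adjusted over the list alone 10 fell and 1 rose. The genes that fell included STARD4 (-1.54 ± 0.29), SREBF2, the transcription factor that drives cholesterol synthesis (-1.54), and MYLIP (-2.39 ± 0.37), a ubiquitin ligase that degrades the LDL receptor, while ABCA1, a cholesterol exporter, rose (2.35 ± 0.47). Toward lower values, the camera adjusted p was 7.55e-05, and adjusted p = 0.363 with an estimated correlation. The list median was -0.34, -0.28, -0.84 and -0.44 in seminal plasma replicates 1 to 4, and without replicates 3 and 4 (camera adjusted p 6.94e-05) STARD4 and MYLIP fell and SREBF2 and ABCA1 did not pass (limma adjusted p 0.224 and 0.158).

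Of 27 measured mitotic and DNA replication genes, none passed, adjusted over all genes or adjusted over the list alone, and MCM2, a subunit of the replicative helicase, had a log2 fold change of -1.94 ± 0.54 (limma adjusted p 0.073). The list's camera adjusted p, in the lower direction, was 0.00562, and adjusted p = 0.363 with an estimated correlation. Its median was -0.14, -0.36, -0.52 and -0.51 in seminal plasma replicates 1 to 4, against -0.25 to 0.22 in the controls, and without replicates 3 and 4 the camera adjusted p was 0.0377. Of 13 measured steroid receptor target genes, 3 fell, with the same count adjusted over the list alone: FKBP5 (-1.2 ± 0.18), TSC22D3 (-1.66 ± 0.32), both induced by glucocorticoids, and the clock gene PER1 (-1.08 ± 0.24). For this list it was 0.0381 in the lower direction, and adjusted p = 0.363 with an estimated correlation. The medians were -0.6, 0.01, -0.53 and -0.71 in seminal plasma replicates 1 to 4, and without replicates 3 and 4 the list did not pass (camera adjusted p 0.201), with FKBP5 down and TSC22D3 and PER1 no longer passing (limma adjusted p 0.147 and 0.177).

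Of the 9 lists that passed the camera test with all arrays, 7 also passed with limma's fry. The mitotic and steroid receptor lists did not (fry adjusted p 0.0695 and 0.0503). Without replicates 3 and 4 none of the lists passed with an estimated correlation in this comparison, where the smallest adjusted p was 0.206. The other lists did not pass the camera test with seminal plasma, although single members did. PTGS2, the inducible cyclooxygenase, rose by 3.09 ± 0.4 (341 to 3120; limma adjusted p 0.00691, and 0.0339 without replicates 3 and 4) as the 1 gene among 17 of prostaglandin synthesis and receptors, with the same count adjusted over the list alone (camera adjusted p 0.854, and 0.58 without replicates 3 and 4). HMOX1, haem oxygenase 1, rose by 3.98 ± 0.69 among 19 NRF2 response genes (camera adjusted p 0.807, and 0.443 without replicates 3 and 4; adjusted over the list alone 2 rose and 2 fell) but had a limma adjusted p of 0.1 without replicates 3 and 4. TNFAIP3 (2.43 ± 0.43), TRAF1 (1.81 ± 0.39) and NFKBIA (0.97 ± 0.21) rose among 17 NF-kappaB targets and feedback genes (camera adjusted p 0.364; 5 up and 1 down adjusted over the list alone), and none of the 3 passed without replicates 3 and 4. The list itself passed there (camera adjusted p 0.0316), and adjusted p = 0.683 with an estimated correlation. Among 28 TGF-beta/SMAD target genes, PMEPA1 and ITGB6 (1.39 ± 0.27) rose and 26 did not pass, with 6 up adjusted over the list alone (camera adjusted p 0.248). That list passed without replicates 3 and 4 (camera adjusted p 0.000921), and adjusted p = 0.378 with an estimated correlation. In 17 hypoxia and glycolysis genes, ANGPTL4, a lipoprotein lipase inhibitor, rose by 3.61 ± 0.6 (camera adjusted p 0.232, and 0.373 without replicates 3 and 4; 3 up and 4 down adjusted over the list alone), with a limma adjusted p of 0.107 without replicates 3 and 4.

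CYP1A1, a xenobiotic-metabolising enzyme induced by the aryl hydrocarbon receptor, fell by 5.53 ± 1.24 on the log2 scale (limma adjusted p 0.0443, and 0.241 without seminal plasma replicates 3 and 4), and passed in 2 of 12 fits that left out 1 array. The size of that change depended on the controls, whose CYP1A1 signals were 330, 304, 5500 and 4980 in replicates 1 to 4. It also depended on the floor of 16, at which 3 of the 4 seminal plasma arrays lay, as they did for RTP4, RCSD1 and LYZ. In addition, 2 control arrays lay at the floor for IL13RA2 and IL11, as did 2 TGFB3 arrays for IL13RA2 and RCSD1. UGT1A6 (-1.13 ± 0.21) was the other of 7 measured receptor targets that fell, with the same count adjusted over the list alone (camera adjusted p 0.106, and 0.174 without replicates 3 and 4). Among 12 basal keratinocyte genes DST fell by 1.57 ± 0.3 (camera adjusted p 0.112, and 0.282 without replicates 3 and 4), among 24 pattern recognition and antigen presentation genes TLR3, a sensor of double-stranded RNA, fell by 1.44 ± 0.26 (0.0809 and 0.423), and among 16 p53 targets SESN1 fell by 1.34 ± 0.3 (0.127 and 0.215). In these 3 lists, adjusted over the list alone, 1 rose and 2 fell, 1 rose and 2 fell, and 2 rose and 5 fell. DST kept its call without replicates 3 and 4 (limma adjusted p 0.0188), and TLR3 and SESN1 did not (0.0779 and 0.212). Among 12 genes of polyamine metabolism ATP13A3 rose by 1.04 ± 0.22, with 5 up and 1 down adjusted over the list alone (camera adjusted p 0.248, and 0.0178 with limma's fry). Without replicates 3 and 4 ATP13A3 did not pass (limma adjusted p 0.109), but the polyamine list did (camera adjusted p 0.0316), and adjusted p = 0.235 with an estimated correlation. Among 15 cAMP-responsive genes PER1 fell, with 2 up and 2 down adjusted over the list alone (camera adjusted p 0.774, and 0.0734 without replicates 3 and 4). No member passed among 27 squamous differentiation genes (camera adjusted p 0.778), 22 cell junction and barrier genes (0.152), 15 antimicrobial and mucin genes (0.774), 17 unfolded protein and stress response genes (0.778) and 12 heat shock proteins (0.854), and adjusted over the list alone 2 heat shock genes rose and 1 fell. These 5 lists did not pass without replicates 3 and 4 either (camera adjusted p 0.23, 0.292, 0.477, 0.282 and 0.282), where the direction of the prostaglandin, junction, NRF2 and heat shock lists turned from lower to higher. The median and mean of the TGF-beta, prostaglandin, NRF2 and heat shock lists differed in sign.

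Markers of other cell types, which would also record RNA carried in with seminal plasma, did not pass the camera test: 11 prostate and seminal vesicle markers (adjusted p 0.248, no member changed), 12 sperm and testis markers (0.778, SPAG16 down by 0.76), 15 leukocyte markers (0.742, LYZ down by 1.52), 10 fibroblast markers (0.27, no member changed) and 12 columnar epithelium markers (0.106, KRT18 up by 0.86). The same counts were obtained adjusted over the list alone. With limma's fry the prostate and columnar lists did pass (adjusted p 0.0244 in both), with 9 of 11 and 10 of 12 members higher. The prostate medians were 0.27, 0.4, 0.61 and 0.4 in seminal plasma replicates 1 to 4, against -0.22 to 0.02 in the controls, and the columnar medians 0.5, 0.37, 0.48 and 0.4, against -0.08 to 0.16. Without replicates 3 and 4 the camera adjusted p was 0.305 for prostate, 0.892 for sperm, 0.437 for leukocyte and 0.104 for columnar markers, and SPAG16, LYZ and KRT18 did not pass (limma adjusted p 0.148, 0.124 and 0.151). The fibroblast list passed there in the lower direction (camera adjusted p 0.0246), and adjusted p = 0.235 with an estimated correlation.

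**Figure D1:**
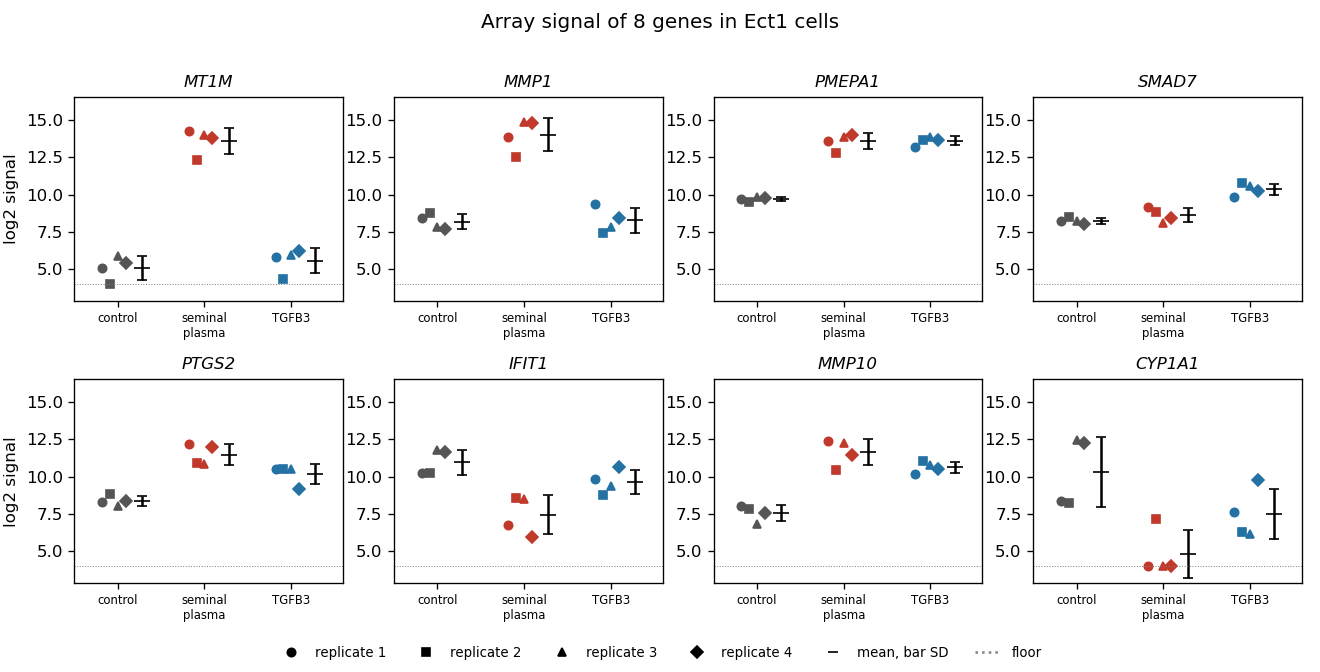
Signal of 8 genes in Ect1 cells (log2 of the linear array signal, vertical axis) on each of the 12 arrays, by treatment, with marker shapes for replicates 1 to 4, the group mean with a bar of 1 SD, and a dotted line at the floor of 16. MT1M and MMP1 lie above all controls on the 4 seminal plasma arrays, PMEPA1 on all 8 treated arrays, and 3 seminal plasma arrays lie at the floor for CYP1A1.

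The second comparison asks which transcripts the recombinant cytokine alone changes. TGFB3 raised established SMAD targets. PMEPA1 went from a mean signal of 834 to 12600, with a log2 fold change of 3.89 ± 0.26 (SE from the spread shared by all 12 arrays). NEDD9, a scaffold of focal adhesions, went from 138 to 1620 (3.42 ± 0.35), and SMAD7, the inhibitory SMAD, from 306 to 1340 (2.1 ± 0.27). KANK4, an adaptor protein at adhesions (4.72 ± 0.72), IGFBP3, an insulin-like growth factor binding protein (3.82 ± 0.54), CHRNA9, a nicotinic receptor subunit (3.62 ± 0.44), MMP10 (3.06 ± 0.42) and the transcription factor FOXL1 (2.95 ± 0.29) rose as well. Fewer genes fell, led by RCSD1 (-2.64 ± 0.43; limma adjusted p 0.0685 without seminal plasma replicates 3 and 4), PIK3R3, a regulatory subunit of phosphoinositide 3-kinase (-1.82 ± 0.27), TBC1D30 (-1.76 ± 0.26), the receptor tyrosine phosphatase PTPRZ1 (-1.68 ± 0.24) and the receptor FGFR3 (-1.67 ± 0.25). PMEPA1, NEDD9, SPOCD1 and FOXL1 also passed in each of 12 fits that left out 1 array, CHRNA9 in 11, SMAD7 and IGFBP3 in 8, MMP10 in 6 and KANK4 in 5. Of the falls, PIK3R3, TBC1D30 and PTPRZ1 passed in 5 of these fits, FGFR3 in 4 and RCSD1 in 2. Of 25 named genes called with TGFB3, 6 passed in all 12 fits, 5 in more than 6 and 14 in 6 or fewer. The TGFB3 transcript itself did not pass (0.15 ± 0.5; limma adjusted p 1), nor did TGFB1 (0.42 ± 0.42; limma adjusted p 0.965).

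With limma, 104 probe sets passed an adjusted p of 0.05, 92 higher and 12 lower, and 56 genes did so, 48 higher and 8 lower. The limma adjusted p was 0.000425 for PMEPA1, 0.00443 for NEDD9, 0.0127 for SMAD7, 0.0317 for KANK4, 0.0221 for IGFBP3, 0.00972 for CHRNA9, 0.0038 for FOXL1 and 0.0463 for RCSD1. Without seminal plasma replicates 3 and 4, which enter the shared estimate of the spread, 296 probe sets passed, 218 higher and 78 lower, and 100 of the 104 remained. Unchanged values simulated with each group's own spread gave a mean of 15.7 probe sets at the same p cutoff, which is 15% of 104. A test with a separate spread per group, which also lacks limma's moderation, called 40 probe sets, 17 of them among the 104. The balance of higher and lower calls moved with the fit: array weights gave 1027 higher and 744 lower, and a fit of the 2 groups alone 205 and 95. The count was 60, 43 and 36 without control replicates 1, 3 and 4, and 36, 35 and 61 without TGFB3 replicates 2 to 4.

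TGF-beta/SMAD target genes rose as a group, with 5 of 28 measured members up and 23 not passing, and 15 up adjusted over the list alone. Besides PMEPA1, NEDD9 and SMAD7, they included ITGB6, an integrin chain that activates latent TGF-beta (2.54 ± 0.27; limma adjusted p 0.00493). The camera adjusted p was 1.11e-17, and 0.0112 with an estimated correlation. Of 25 epithelial-mesenchymal transition and matrix genes, 3 rose and 22 did not pass, and 15 rose adjusted over the list alone. They were COL4A1, a basement membrane collagen (1.64 ± 0.21), LAMB3 (1.63 ± 0.26) and SNAI2 (1.4 ± 0.23). With 1 array left out COL4A1 passed in 7 of 12 fits, and LAMB3 and SNAI2 in 3 each. The camera adjusted p was 1.15e-16, and 0.00761 with an estimated correlation. Fitted without seminal plasma replicates 3 and 4, each of these lists had 7 members up, with camera adjusted p values of 1.25e-16 and 2.19e-14, and adjusted p = 0.0676 with an estimated correlation in both.

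A further 7 lists passed the camera test with TGFB3, and none of them did so with an estimated correlation. Of 21 matrix protease genes MMP10 alone rose, with 6 up adjusted over the list alone (camera adjusted p 1.28e-06, and adjusted p = 0.059 with an estimated correlation). Of 28 inflammatory cytokines and chemokines none passed, with 4 up adjusted over the list alone (camera adjusted p 2.35e-06, and adjusted p = 0.246 with an estimated correlation). IL6 (1.78 ± 0.42; limma adjusted p 0.182) and IL11 (3 ± 0.63; limma adjusted p 0.129) had the largest evidence in that list, whose median was 0.71, 1.13, 1.14 and 0.01 in TGFB3 replicates 1 to 4. No member passed among 17 unfolded protein and stress response genes (camera adjusted p 0.000363 in the higher direction, and adjusted p = 0.246 with an estimated correlation), 17 NF-kappaB genes (0.00596, higher, and adjusted p = 0.71 with an estimated correlation), 17 hypoxia and glycolysis genes (0.00688, higher, and adjusted p = 0.71 with an estimated correlation), 27 interferon-stimulated genes (3.03e-06, lower, and adjusted p = 0.504 with an estimated correlation) and 23 cholesterol genes (0.0297, lower, and adjusted p = 0.71 with an estimated correlation). In these 5 lists, adjusted over the list alone, 2 hypoxia genes rose, 1 cholesterol gene fell and the others held none. The NF-kappaB median was 1.34 and 1.28 in TGFB3 replicates 2 and 3, but -0.09 and -0.27 in replicates 1 and 4. The hypoxia median was 0.85 and 0.69 in TGFB3 replicates 2 and 3, but 0.29 and -0.11 in replicates 1 and 4, within the range of -0.41 to 0.37 of the controls. The cholesterol median was 0.01 in TGFB3 replicate 4, within the range of -0.05 to 0.1 of the controls. Without seminal plasma replicates 3 and 4 the cholesterol list no longer passed (camera adjusted p 0.0619), while the other 6 did.

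The other 21 lists did not pass with TGFB3, with or without seminal plasma replicates 3 and 4. IER3 rose (1.34 ± 0.2; limma adjusted p 0.0317) as the 1 member among 19 EGF receptor and MAPK feedback genes (camera adjusted p 0.0678), and GADD45A rose (1.72 ± 0.19; limma adjusted p 0.00643) as the 1 member among 16 p53 targets (camera adjusted p 0.842), with 1 and 3 up adjusted over the list alone. With 1 array left out IER3 passed in 4 of 12 fits and GADD45A in 12. PTGS2 had a log2 fold change of 1.79 ± 0.4 that did not pass (limma adjusted p 0.156), and adjusted over the list alone 2 prostaglandin genes rose (camera adjusted p 0.772). Metallothioneins and zinc transport genes held no change (camera adjusted p 0.105, and none adjusted over the list alone), with MT1M at 0.48 ± 0.56 and MT2A at 0.29 ± 0.27. Median, mean and test direction differed in sign for the prostaglandin, cAMP, pattern recognition, squamous, basal keratinocyte, p53, steroid receptor and fibroblast lists.

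The third comparison sets the treatments against each other. MT1M (8.01 on the log2 scale), MMP1 (5.73), IL13RA2 (4.58), RPPH1, the RNA component of ribonuclease P (3.8), and SLC30A2, a zinc transporter (3.41), were higher with seminal plasma than with TGFB3. For RPPH1 all 4 TGFB3 arrays lay at the floor. The Notch-modifying enzyme LFNG (-3.59), KCTD11 (-3.49), OLR1, a receptor for oxidised lipoprotein (-3.48), PNRC1 (-3.44) and ID3, an inhibitor of helix-loop-helix factors (-3.34), were lower with seminal plasma. In TGFB3 replicates 1 to 4 the signal was 1190, 4370, 4300 and 1070 for KCTD11, and 806, 5750, 6440 and 891 for OLR1. Both differences were thus larger in TGFB3 replicates 2 and 3 than in replicates 1 and 4. SMAD7 was lower with seminal plasma than with TGFB3 by 1.71 (limma adjusted p 0.0233), and so was NEDD9 (-1.98; 0.0305), whereas PMEPA1 differed by -0.03 (0.957). Without seminal plasma replicates 3 and 4, MT1M (7.72), MMP1 (4.91), IL13RA2 (4.33), LFNG (-4.03) and PNRC1 (-2.08) still passed. RPPH1 (2.8), SLC30A2 (2.99), KCTD11 (-2.86), OLR1 (-2.79), ID3 (-2.04), SMAD7 (-1.33) and NEDD9 (-1.8) did not (limma adjusted p 0.217, 0.195, 0.132, 0.218, 0.0862, 0.0673 and 0.131). Of 35 named genes called here, 6 passed in all 12 fits that left out 1 array, MT1M, MMP1, IL13RA2 and LFNG among them, 10 in more than 6 and 19 in 6 or fewer. SMAD7 passed in 8, KCTD11 and NEDD9 in 4, PNRC1, ID3, OLR1 and SLC30A2 in 2 and RPPH1 in 1.

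With limma, 945 probe sets passed an adjusted p of 0.05, 519 higher and 426 lower with seminal plasma, and 383 genes did so. The limma adjusted p was 0.000653 for MT1M, 0.00356 for MMP1, 0.00544 for IL13RA2, 0.0117 for LFNG and 0.0369 for ID3. The count was 394 without seminal plasma replicates 3 and 4, of which 212 were among the 945, and after median centring 369 passed, 119 higher and 250 lower. Unchanged values simulated with each group's own spread gave a mean of 271.3 probe sets at the same p cutoff, which is 28.7% of 945. A test with a separate spread per group, which also lacks limma's moderation, called 0. It had 5865 at an unadjusted p under 0.05, against 12196 with limma. The count was 489, 360, 296 and 282 without control replicates 1 to 4, 7055, 450 and 177 without seminal plasma replicates 2 to 4, and 409, 110, 91 and 159 without TGFB3 replicates 1 to 4.

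Metallothioneins and zinc transport genes were higher with seminal plasma than with TGFB3, with 5 of 11 up and 1 down, and 9 up and 1 down adjusted over the list alone (camera adjusted p 1.94e-06, and adjusted p = 0.17 with an estimated correlation). TGF-beta/SMAD target genes were lower, with 5 of 28 down and 9 down and 1 up adjusted over the list alone (camera adjusted p 3.93e-07, and adjusted p = 0.17 with an estimated correlation). CDKN2B, a cell cycle inhibitor (-2.45), and TGFBR1, a TGF-beta receptor (-1.19), were among the 5. Epithelial-mesenchymal transition and matrix genes were lower as a list (camera adjusted p 0.00055, and adjusted p = 0.252 with an estimated correlation), although of 25 members only LOX, which crosslinks collagen, was lower (-3.2) and TAGLN was higher (1.46), with 11 down and 1 up adjusted over the list alone. The interferon-stimulated genes were lower too, with 2 of 27 down, OASL (-2.04) and IFIH1 (-0.88), and 4 adjusted over the list alone (camera adjusted p 0.00054, and adjusted p = 0.377 with an estimated correlation). In each of these 4 lists the camera test passed without seminal plasma replicates 3 and 4, where 3 metallothionein and zinc genes were higher and no member of the other 3 lists passed.

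A further 9 lists were lower with seminal plasma than with TGFB3, and none passed with an estimated correlation, at which the adjusted p was 0.377 for hypoxia genes, mitotic genes, steroid receptor targets, cholesterol genes, pattern recognition genes and stress response genes, 0.487 for junction genes, and 0.334 for p53 targets and basal keratinocyte genes. Their camera adjusted p was 0.00145 for hypoxia, 0.00657 for mitosis, 0.00687 for steroid receptor targets, 0.00889 for junctions, 0.0121 for cholesterol, 0.016 for p53 targets, 0.0341 for pattern recognition, 0.0345 for stress response and 0.0351 for basal keratinocyte genes. Their single members past the threshold were few: TSC22D3 (-2.05) and FKBP5 (-1.11) among steroid receptor targets, STARD4 (-1.74) for cholesterol, GADD45A (-1.15) for p53 and XBP1 (-1.06) for stress response. Adjusted over the list alone, 4 basal keratinocyte genes, 3 genes each of the steroid receptor, hypoxia and cholesterol lists, 2 stress response genes and 1 p53 target were lower. Without seminal plasma replicates 3 and 4, the camera test of the mitotic, junction, pattern recognition, stress response and basal keratinocyte lists no longer passed (adjusted p 0.0715, 0.684, 0.755, 0.162 and 0.071). There, 1 steroid receptor target and 1 cholesterol gene were lower, and no p53 target or stress response gene passed. In the same fit 4 lists that had not passed did so: EGF receptor and MAPK feedback genes (camera adjusted p 6.25e-05, and adjusted p = 0.412 with an estimated correlation), heat shock proteins (0.0153, and adjusted p = 0.515 with an estimated correlation) and NRF2 genes (0.0232, and adjusted p = 0.515 with an estimated correlation), all higher, and fibroblast markers (0.0169, and adjusted p = 0.342 with an estimated correlation), lower.

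**Figure D2:**
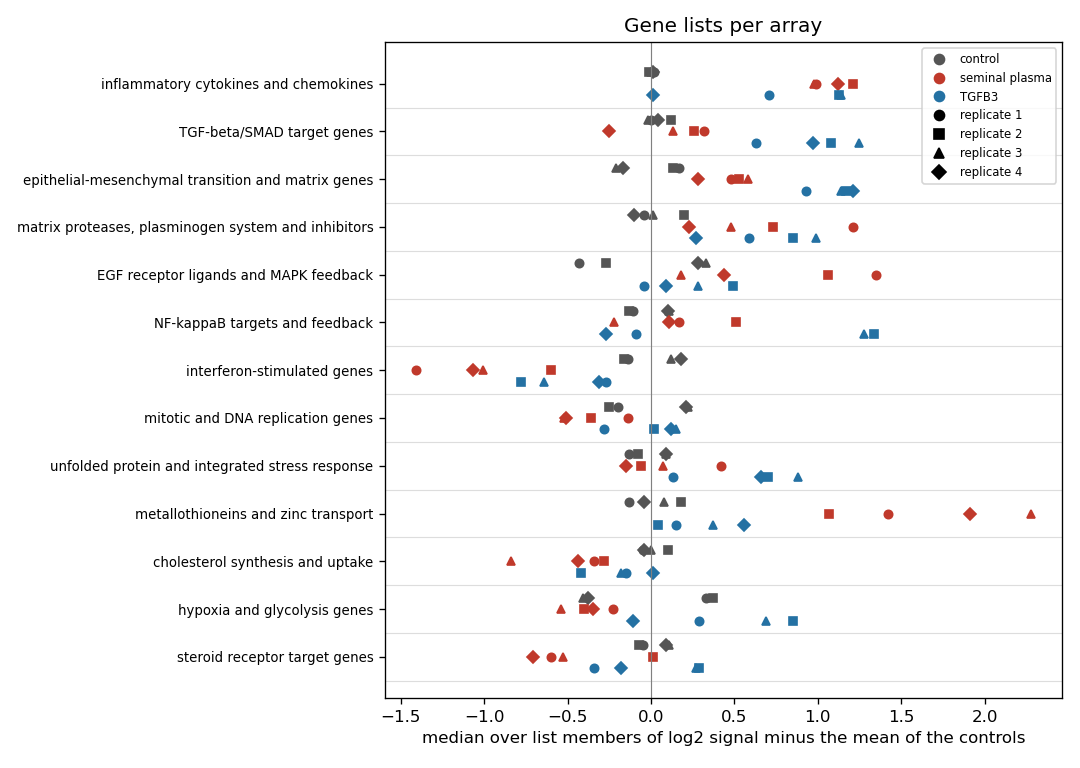
Median over the members of each gene list (horizontal axis, log2 signal minus the mean of the 4 controls) on each of the 12 arrays, for the lists that passed the camera test against control with either treatment. Colours give the treatment and marker shapes replicates 1 to 4. Metallothioneins lie at 1.07 to 2.28 on the seminal plasma arrays, and TGF-beta/SMAD targets at 0.63 to 1.25 on the TGFB3 arrays.

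Genes that passed with both treatments were counted to see how far the profiles overlapped. Of the 56 genes called with TGFB3, 30 were called in the same direction with seminal plasma, 26 higher and 4 lower. The shared rises included PMEPA1, SPOCD1, MMP10, FOXL1, IGFBP3, ITGB6, LAMB3, IER3 and SNAI2, and the shared falls were RCSD1, PIK3R3, FGFR3 and RASSF5. No gene was called in opposite directions, and 19 of the 56 differed between the treatments in the direct test. Independent lists of these sizes would share 0.88 higher and 0.11 lower genes, and simulated unchanged groups set against the same 4 controls shared 0.08 and 0.07. With nothing changed, few genes are called in such draws, so a small overlap was built in. The draws do not show how much the shared controls add at the real number of calls. With the controls split between the comparisons, 2 to each, a mean of 5 higher and 0.2 lower genes were shared. The split also leaves each comparison fewer controls, which costs power. Leaving out only 1 control, as given below, cut the count as well. The drop therefore does not show what the shared controls add either. In the fit without seminal plasma replicates 3 and 4, 39 genes were shared, but only 16 of the 30 were among them, and IGFBP3, SNAI2, PIK3R3 and RCSD1 were among the 14 that were not. RCSD1 lost its call with TGFB3, and the other named genes with seminal plasma. Their log2 fold changes with seminal plasma were 3.08 (IGFBP3), 0.57 (SNAI2) and -1.4 (PIK3R3) in that fit, against 2.92, 0.98 and -1.7 with all arrays. The count was 17, 17, 10 and 9 without control replicates 1 to 4, 15 without seminal plasma replicate 4, and 10, 10 and 17 without TGFB3 replicates 2 to 4.

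Across 19682 genes, which are not independent replicates, the log2 fold changes of the treatments had a Pearson correlation of 0.43, against 0.376 in simulated unchanged groups with shared controls. The measured arrays with the controls split, and so not shared, gave a mean correlation of 0.216. This is not a value for unchanged groups. Their covariance was 0.163 against a simulated 0.0603, a difference of 0.103. On the measured arrays with the controls split, the mean covariance was 0.0966. The correlation was 0.464 without seminal plasma replicates 3 and 4.

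**Figure D3:**
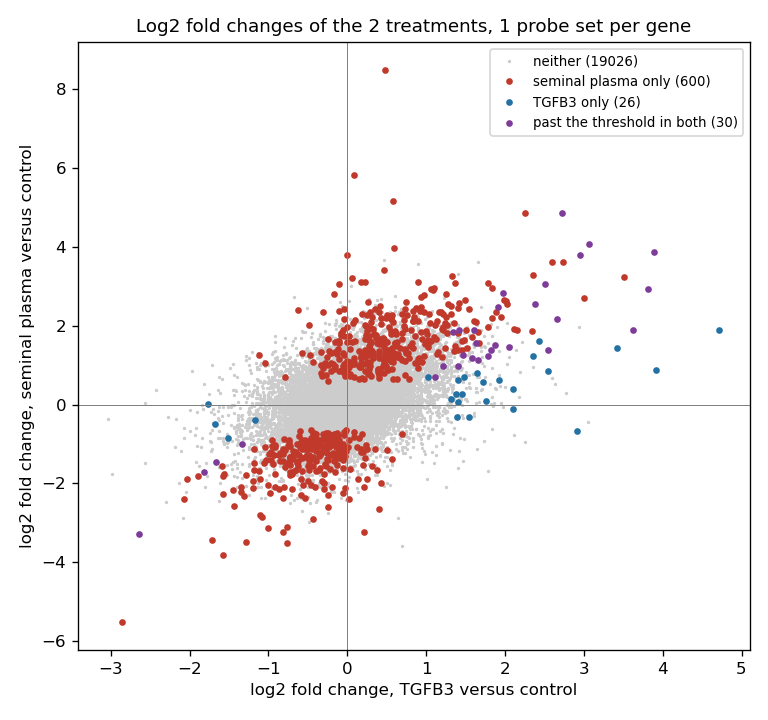
Log2 fold change against control of each of 19682 genes, TGFB3 on the horizontal axis and seminal plasma on the vertical axis, with colours for the genes that passed a limma adjusted p of 0.05 with either treatment or both. The 30 genes that passed in both lie at the upper right (26) and lower left (4), and MT1M, at 0.48 and 8.49, lies highest.

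In the authors' deposited table, 3955 probe sets were called for seminal plasma, 2284 higher and 1671 lower, and 884 for TGFB3, 592 higher and 292 lower. Every call in the authors' deposited table had a fold of at least 2, a p of at most 0.0499 and a difference in mean signal of at least 100. Of the 1608 limma calls for seminal plasma, 1075 (66.9%) were also calls in the authors' deposited table, and of the 104 for TGFB3, 97 (93.3%) were, all in the same direction. In the authors' deposited table MT1M had a fold of 385.61 and MMP1 one of 64.56 with seminal plasma, and PMEPA1 one of 15.05 with TGFB3. At 1 probe set per gene, the authors' deposited table called 1304 genes for seminal plasma and 429 for TGFB3, with 160 in both and 153 of those in the same direction.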

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

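The tests of technical explanations below were chosen after the results were seen, except the array-wide scaling and the other splits of the arrays, which were planned before.

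Seminal plasma replicates 3 and 4 lay far from the other arrays. Array-wide scaling is excluded as the whole cause, since after quantile normalization their mean absolute deviation from the control mean was still at least 1.79 times that of replicates 1 and 2 (1.7 before). Loss of signal that depends on the probe set, as from RNA quality or labelling, was left standing: 2 probe sets of the same gene differed in their shift with an SD of 1.44 and 1.3 in replicates 3 and 4, against 0.59 and 0.36 in replicates 1 and 2, a ratio of at least 2.21. This difference correlated at 0.89 between replicates 3 and 4, against 0.56 between replicates 1 and 2. A change of whole genes in these cultures could not be told apart (correlation between 2 probe sets of a gene at most 0.31, against 0.39 to 0.82 on the other 10 arrays). No biological explanation was tested.

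Control replicates 3 and 4 and TGFB3 replicate 4 deviated from their groups together, first seen in CYP1A1, whose signal was 330, 304, 5500 and 4980 in the controls and 879 in TGFB3 replicate 4, with a lowest TGFB3 value of 72.5. A shared culture run or array batch was left standing, though the labels name none: outside the aryl hydrocarbon receptor genes, TGFB3 replicate 4 correlated with control replicates 1 to 4 at -0.22, -0.25, 0.29 and 0.28. TGFB3 replicate 1 did so at 0.3, 0.16, -0.27 and -0.3, and since deviations within a group sum to 0, the negative values add no separate support. A control sample labelled as TGFB3 replicate 4 is excluded, since SMAD7 and PMEPA1 lay at least 1.76 (log2) above the highest control in it. No biological explanation was tested.

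The rise of metallothionein and zinc transport genes with seminal plasma was weighed too. Signal shared between the similar metallothionein copies is excluded as the whole cause, because SLC30A1, which is no metallothionein, rose by 2.27. Shared signal may decide which copies appear to rise, since 6 of the 7 were read by a probe set marked as shared. The state of seminal plasma replicates 3 and 4 is excluded as the whole cause, because replicates 1 and 2 alone had list medians of at least 1.07. Its part in the size of the rise stays open, since the list medians were 2.28 and 1.91 in replicates 3 and 4. The zinc in seminal plasma is a biological candidate that the design cannot test.

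The counts of probe sets were set beside those from other assignments of the arrays to groups. Over 35 splits of the 8 arrays into 4 and 4, the real split ranked 1 in each comparison, with 1608 against at most 2 for seminal plasma, 104 against at most 2 for TGFB3, and 945 against at most 27 between the treatments. No share below 1 in 35 can be reached this way. The other splits mix the groups, so that a real difference widens their spread and lowers their counts. The ranks thus do not exclude chance, and they do not tell how many calls are false.

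Single arrays far from the other 3 of their group were found in 24 of 411 groups of named genes, where chance alone gives about 1 in 20, or 20.6. In seminal plasma replicate 2 they were CYP1A1 (7.2, others 4 on the log2 scale), RPPH1 (4.76, others 8.68 to 8.9), USP18 (6.82, others 4 to 4.43), OAS2 (9.31, others 7.31 to 7.54) and SPAG16 (9.77, others 9.36 to 9.42). Replicate 3 held RTP4 (4.37), RCSD1 (4.05) and LYZ (4.43), each with the others at the floor of 4, and replicate 4 held UGT1A6 (6.58, others 7.24 to 7.35), COL1A2 (6.97, others 4.55 to 4.81) and TGFB1 (8.94, others 9.97 to 10.08).

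TGFB3 replicate 1 held ZNF488 (6.64, others 7.68 to 7.84), FOXL1 (8.04, others 8.55 to 8.57), COL4A1 (10.61, others 11.23 to 11.35), LCE3D (9.23, others 8.13 to 8.29) and MSMB (7.27, others 5.34 to 5.56). TGFB3 replicate 4 held PTGS2 (9.17, others 10.51 to 10.52) and MUC15 (5.79, others 4). Among the controls, replicate 1 held TBC1D30 (7.52, others 7.7 to 7.73), PTPRZ1 (9.27, others 9.56 to 9.61) and CSF1R (8.81, others 8.18 to 8.23). Control replicate 2 held SNAI2 (12.28, others 12.09 to 12.12), replicate 3 ATF3 (9.06, others 9.4 to 9.44) and replicate 4 PER1 (10.5, others 10.29 to 10.32).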

How the results depend on the processing

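The fits without seminal plasma replicates 3 and 4, the floors of 32 and 100 and the separate spread per group were chosen after the data were seen, and the other alternatives before. In the fits that tested genes and lists, no named gene or list that passed as reported or under an alternative changed direction, while some that passed in neither did. The named genes were put through them for the direct contrast of the treatments after its values were seen. Counts are given in the order seminal plasma versus control, TGFB3 versus control and seminal plasma versus TGFB3, against 1608, 104 and 945. The dim filter (1614, 96, 817) and quantile normalization (1232, 132, 849) stayed within 1.5 times. Median centring gave 787, 61 and 369, and an intensity trend with robust estimation 3666, 228 and 2352. A threshold of 0.01, which is stricter by construction, left 109, 34 and 41. With only the 2 groups compared, the counts were 197, 300 and 12, and so higher for TGFB3 versus control but lower in the other comparisons. Without seminal plasma replicates 3 and 4 they were 539, 296 and 394. With a separate spread per group and no moderation they were 11, 40 and 0 (7288, 5374 and 5865 at an unadjusted p under 0.05). Array weights gave 1771 (1027 higher, 744 lower) for TGFB3. Leaving out probe sets marked as shared gave 867 for seminal plasma and 434 between the treatments. A floor of 32 gave 167 for TGFB3 and 1454 between the treatments, and a floor of 100 gave 160 for TGFB3. Except where the construction is named, the cause was not tested.

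The genes called with both treatments numbered 30, but 54 with the mean of all probe sets of a gene and 50 with a floor of 32. Of 9, 9 and 13 lists past the camera test, 0, 2 and 0 passed with an estimated correlation. Directional fry called 10 for seminal plasma, 3 for TGFB3 and 8 between the treatments, of which 7, 3 and 6 had passed the camera test. Mixed fry called 25 for seminal plasma and 26 between the treatments, and the mean of all probe sets gave 15 for seminal plasma.

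With the replicate number as a block, the counts were 307, 21 and 47, 6 genes were called with both treatments, and 22 of 66, 3 of 25 and 6 of 35 named genes kept their call. Whether the numbers pair the arrays stayed open. Arrays of the same number had residual correlations between -0.18 and 0.3, and not every array correlated best with its own number. Control and TGFB3 arrays correlated at 0.3 for replicate 1 and 0.29 for replicate 4, but at -0.02 and -0.01 for replicates 2 and 3.

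Leaving out each array in turn gave 270 (without control replicate 4) to 8900 (without seminal plasma replicate 2) probe sets for seminal plasma, 35 (without TGFB3 replicate 3) to 142 (without seminal plasma replicate 3) for TGFB3, and 91 (without TGFB3 replicate 3) to 7055 (without seminal plasma replicate 2) between the treatments. It gave 9 to 41 genes called with both. The lists past the camera test ranged over 6 to 10, 6 to 11 and 9 to 16, and the correlation of the log2 fold changes over 0.378 to 0.475. Of 66 named genes called with seminal plasma, 53 kept the call after quantile normalization, 44 after median centring, 52 with a floor of 100 and 27 without seminal plasma replicates 3 and 4. Of 25 called with TGFB3, 23, 15, 23 and 24 did, and of 35 between the treatments 31, 22, 30 and 12. Weak signals limit the smallest changes, since 8.01% to 20.2% of probe sets per array lay below the floor.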

Other observations

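The genes in this part were chosen after their values were seen. Among the genes that rose with both treatments were secreted regulators outside the lists. PTHLH, which encodes parathyroid hormone-related protein, rose by 2.84 ± 0.18 on the log2 scale with seminal plasma (limma adjusted p 0.000149, and 0.0021 without seminal plasma replicates 3 and 4) and by 1.97 ± 0.18 with TGFB3 (0.00225). INHBA, the subunit of activin A, another member of the TGF-beta family, rose by 3.06 ± 0.41 (0.00897, and 0.0609 without those replicates) and 2.51 ± 0.41 (0.0486, and 0.055 without those replicates), and so passed with neither treatment in that fit. WNT9A, a Wnt ligand, rose by 2.47 ± 0.31 (0.0063, and 0.0255 without those replicates) and 1.91 ± 0.31 (0.0463).

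Transcripts of proteins that are not secreted rose with both treatments as well. G0S2, an intracellular inhibitor of lipid breakdown, rose by 2.56 ± 0.27 with seminal plasma (limma adjusted p 0.00212) and 2.38 ± 0.27 with TGFB3 (0.00674), MICAL2, which oxidises actin, by 1.89 ± 0.16 (0.000413) and 1.42 ± 0.16 (0.00643), and the receptor tyrosine phosphatase PTPRK by 1.47 ± 0.18 (0.00635) and 2.05 ± 0.18 (0.00159). All 3 also passed with seminal plasma without replicates 3 and 4 (adjusted p 0.0053, 0.00423 and 0.0326).

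The control arrays differed among themselves in lists that did not pass with seminal plasma. The median of squamous differentiation genes was 0.55, 0.44, -0.58 and -0.39 in control replicates 1 to 4, that of antimicrobial and mucin genes 0.61, 0.4, -0.52 and -0.25, and that of hypoxia and glycolysis genes 0.33, 0.37, -0.41 and -0.38. CYP1B1, like CYP1A1 an aryl hydrocarbon receptor target, had signals of 519, 422, 4320 and 3870 in control replicates 1 to 4, of 314, 487, 795 and 654 with seminal plasma, and of 453, 519, 431 and 3570 with TGFB3.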
